A study of Mus musculus with 3 samples.

How the data were processed

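Spleens of 12 naive C57BL/6 mice were pooled and 3 populations, labelled T, DC and TDC, were sorted from them, with 1 array each. Per the labels' protocols, cells were stained for CD11c, MHC class II and the T cell receptor beta chain and sorted in repeated rounds to a purity of at least 99%. RNA of 1000 to 4000 sorted cells was isolated with the RNeasy Micro kit, amplified with the NuGEN WT-Ovation kit and hybridised to Affymetrix mouse arrays, also per the labels' protocols. Partek 6.6 is named per the submitters' processing notes. The deposited values are linear signal intensities of probe sets, and the algorithm and scaling that made them are not given in the sources used here. From the values themselves, the mean after trimming 2% of probe sets at each end is 500 on each array, as a global scaling of each array would give. Raw image data were not used here.

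Values were taken as log2 with no pseudocount and no further scaling. Of 45101 probe sets, 64 are controls, 34958 carry a single gene symbol, 932 carry several and 9211 are not listed with a gene. Of the single-symbol probe sets, 34754 were matched by Entrez identifier. A gene was represented by its probe set with the highest mean over the 3 arrays among single-symbol probe sets, which gave 18194 genes, 9012 of them with at least 2 probe sets. Background on an array was the 95th percentile of the probe sets of a fixed list of genes of other tissues (114 on T, 107 on DC and 118 on TDC). In place of sequencing depth, 13999 of the probe sets on T, 18719 on DC and 13097 on TDC were above background, with a median signal of 28.6, 47.0 and 38.9. The 24 poly-A control probe sets had a mean signal of 17219, 5666 and 19061, and the ratio of 3′ to 5′ signal of Gapdh was 4.15, 2.86 and 7.38.

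The arrays were compared as DC with T, TDC with T and TDC with DC. With 1 array per population no test was made and no p-value computed. A gene was counted when the brighter array was above background and the log2 difference was at least 2 (4-fold). Where the dimmer array was below background, the fold is given against background, as "at least". The precision is that of a single array: the spread between probe sets of a gene stands in for technical noise and says nothing of biological spread. The place of TDC between T and DC was (TDC - T)/(DC - T) on the log2 scale, called near T under 1/3 and near DC over 2/3, beside 100 simulated arrays equal to T or to DC plus noise of the SD of 1 array, and again, added after the data were seen, of the SD of a difference. A median share of the level on T or DC was taken on the linear scale, with 10000 bootstrap draws over genes.

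Each of 38 gene lists, written from general knowledge with 671 entries found on the arrays and 82 not, was described by the counts of its genes and by the percentile of its median log2 difference among 10000 random lists of the same size, matched on mean level in 10 bins. List genes count as measured when above background on any of the 3 arrays. Lists are not independent, since genes occur in more than 1 list. Named genes were chosen by rule: the 10 with the largest difference in each direction of each comparison, counted against background where needed, among genes whose other detected probe sets go the same way by at least 1 (log2), the 10 highest and 10 lowest on TDC against both others, and up to 4 genes of each list with the largest difference, with all sort markers and coreceptors. The comparisons, the 4-fold rule, background, lists, naming rule and most alternatives were set before the data were examined.

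The alternatives were quantile normalisation, centring on genes above background on all arrays, background at the median probe set or no background, the mean of all probe sets of a gene, leaving out probe sets marked as cross-hybridising, 2-fold and 8-fold thresholds, and a linear scale of the place. Scaling to the 18 hybridisation control probe sets, a demand for at least 2 agreeing probe sets, and the MHC class II and core dendritic cell lists without the sort marker genes were added after the data were seen. The method was tested on simulated data: with the median noise, 54%, 46% and 52% of genes that differed 4-fold were called for DC with T, TDC with T and TDC with DC, and 98%, 100% and 100% of genes that differed 16-fold (48%, 56% and 56%, and 94% each, with the pooled noise). The 4-fold values were fixed by the design, since symmetric noise calls a difference equal to the cutoff about as often as not. Of 200 random lists of 15 genes, 6 lay outside the central 95%. An even mixture of T and DC gave a sum of shares of 1.01. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.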

Results

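Gene expression was measured on oligonucleotide arrays in 3 cell populations sorted from the spleens of naive C57BL/6 mice, an inbred laboratory strain. The populations are labelled T (T cells), DC (dendritic cells) and TDC. The labels do not spell out TDC, so it is called here the population labelled TDC. Cells had been stained for CD11c, MHC class II and the beta chain of the T cell receptor, but the combination of stains that defined each population is not given in the sources used here. Each population has 1 array, made from cells of 12 pooled mice. There are thus no replicates: nothing measures the spread between animals or sorts, no difference below could be tested, and the number of arrays limits the precision. Of 18194 genes, 7105 were above background on the T array, 8849 on the DC array and 6906 on the TDC array. The arrays also differed technically. The 18 hybridisation control probe sets had a mean signal of 6091 on T, 3462 on DC and 8541 on TDC. The ratio of 3′ to 5′ signal of the Actb control, which grows as RNA or its amplified copies are truncated, was 2.94 on T, 2.01 on DC and 4.63 on TDC.

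The genes behind the sort were examined first, as a check of the labels. Itgax, which encodes CD11c, had a signal of 8891 on the DC array and 6843 on the TDC array, against 16.1 on the T array, which is below the background of 114 there. The class II genes H2-Aa, H2-Ab1 and H2-Eb1 had signals of 10528, 10306 and 11786 on DC and of 17928, 11159 and 14932 on TDC. On T they had signals of 148, 62.3 and 108. The T cell receptor beta chain was represented in the fixed list by the variable segment Trbv13-2 alone, which had a signal of 1742 on T and was below background on DC (3.32) and TDC (36.0). The 2 probe sets of the segment Trbv1, named after their values were seen, had signals of 16683 on T, 263 on DC and 15950 on TDC, for a probe set marked as able to cross-hybridise, and of 800, 3.51 (below background) and 141 for the other. The listed probe set of Tcra was below background on all 3 arrays. A probe set specific to a variable segment measures only the cells that use it. This need not hold for the Trbv1 probe set that can cross-hybridise, and what else it measured is not known here.

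The comparison of DC with T shows how far the conventional populations lie apart. MHC class II genes were higher on the DC array: 12 of 14 measured genes of the MHC class II list were at least 4-fold higher, with a median log2 difference of 6.03 (4.37 with values below background raised to it). The list holds H2-Aa, H2-Ab1 and H2-Eb1, for which the sort selects, and without them 9 of 11 were higher. Cd74, the invariant chain that guides class II molecules, had a signal of 13407 on DC and 101 on T and was at least 118-fold higher. H2-Ab1 was at least 90.5-fold and Marchf1, a ubiquitin ligase that controls class II turnover, at least 35.1-fold higher. T cell receptor genes were lower on DC: 18 of 21 genes of the complex and its proximal signalling were at least 4-fold lower, among them Prkcq, a protein kinase C of T cells, by at least 97.1-fold, Themis by at least 55.6-fold and Cd6 by at least 52.3-fold. Over all genes, 2793 were at least 4-fold higher on DC and 1174 at least 4-fold higher on T. The counts use the measured values, and 2080 and 556 of these genes were below background on the dimmer array, where the fold above background can be smaller than 4.

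By the naming rule, the genes farthest apart on the DC side were, beside Cd74, H2-Ab1, H2-Eb1 (at least 103-fold), H2-DMb2 (at least 86.4-fold) and Itgax (at least 78.1-fold), Cd83, a dendritic cell maturation marker (at least 102-fold), and Rgs1, a regulator of G protein signalling (at least 98.7-fold). Ptgs2, the inducible cyclooxygenase, was at least 90.5-fold higher, Pmaip1, a pro-apoptotic protein, at least 89.2-fold and Atf3, a stress-induced transcription factor, at least 82.3-fold. On the T side they were the transcription factors Bcl11b (at least 131-fold) and Lef1 (at least 106-fold), the CD3 chains Cd3e (115-fold) and Cd3d (at least 106-fold), and the receptor alpha segment Trav9d-3 (at least 109-fold). Nlrc3, a negative regulator of immune signalling, was at least 108-fold, Gimap3 102-fold, Sntb1 at least 97.0-fold and Cnn3 at least 88.4-fold higher on T. For Cnn3 the log2 difference was -1.25 once probe sets that can cross-hybridise were left out.

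Of the core dendritic cell list, 12 of 17 genes were at least 4-fold higher on DC and 0 lower, with Flt3, the receptor of a dendritic cell growth factor, at least 33.8-fold and Bcl11a at least 47.5-fold higher. The lists of conventional DC type 1 (11 of 14) and type 2 (9 of 13) had such genes too, among them Wdfy4, needed for cross-presentation, at least 67.0-fold and Sirpa 41.6-fold higher. So did costimulation and DC maturation (12 of 14, Il12b at least 9.96-fold), pattern recognition receptors (15 of 20 and 1 lower, Clec7a at least 40.7-fold) and chemokines with their receptors (14 of 23 and 3 lower, Cxcl16 at least 14.7-fold). Of the T lineage transcription factors 6 of 11 were at least 4-fold lower on DC and 1 higher, and of the naive T cell list 5 of 8 were lower, with Il7r, the interleukin-7 receptor, 15.9-fold lower. The lists of NK cells (4 of 12 genes higher, 4 lower), B cells (5 of 10 and 1), plasmacytoid DC (5 of 12 and 1), plasma cells (2 of 6 and 0) and T cell activation and effector genes (5 of 22 and 7) had medians within the central 95% of random lists. Genes of other cell types and of handling differed as well. The monocyte and macrophage list had 11 of 14 genes at least 4-fold higher on DC, with C1qb at least 50.8-fold. The immediate early and sorting stress list had 12 of 23, with Nr4a2 at least 54.6-fold and Fosb at least 36.8-fold, and the cell cycle list 11 of 24. The neutrophil list had 1 of 11 genes at least 4-fold higher and 7 lower on DC, and the count of lower genes was 0 after scaling to the hybridisation controls.

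No test was possible for these differences. The median of 13 of 36 lists lay above the central 95% of 10000 random lists of matched size and level, and that of 6 below it, as a description of this pair of arrays; the 13 include the sort marker list, whose outcome the sort fixed. The log2 differences of probe sets of one gene had an SD of 1.25 pooled over genes and 0.78 as the median over genes. In simulated arrays that differed by such noise alone, 649 unchanged genes were called higher and 322 lower with the pooled SD, and 56 and 34 with the median SD. Of all calls, 70.4% were higher on DC as deposited, 56.8% after quantile normalisation and 83.6% after scaling to the hybridisation controls.

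**Figure D1:**
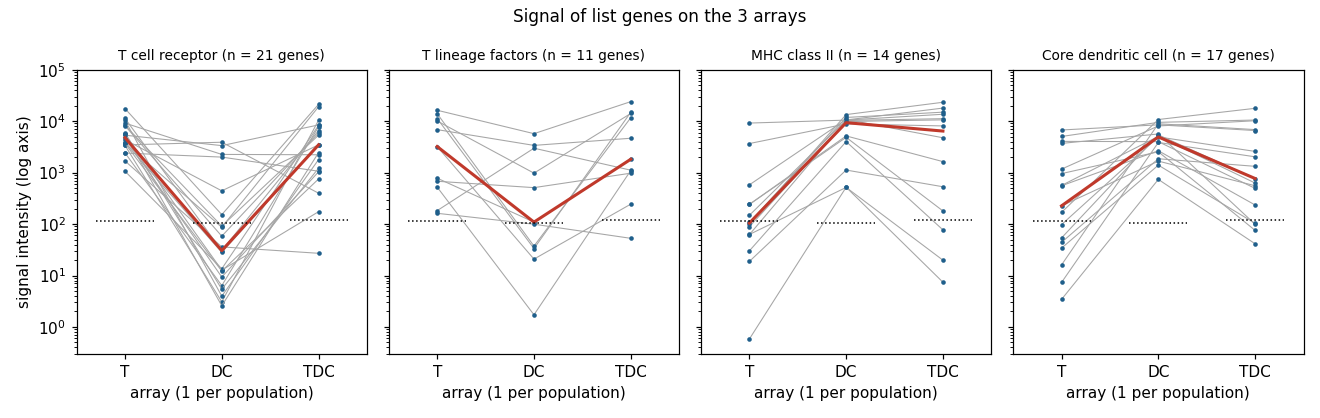
Signal intensity (log axis) of each measured gene of 4 lists on the T, DC and TDC arrays, 1 array per population. Grey lines join the values of 1 gene, the red line joins the medians and dotted lines mark background; 16 of 21 T cell receptor genes are at least 4-fold higher on TDC than on DC, and 8 of 14 MHC class II genes at least 4-fold higher on TDC than on T (5 of 11 without those for which the sort selects).

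The comparison of TDC with T asks which genes set the TDC population apart from T cells. Of the MHC class II list 8 of 14 genes were at least 4-fold higher and 0 lower on the TDC array, and 5 of 11 without the 3 genes for which the sort selects, with Cd74 at a signal of 23250 (at least 204-fold), H2-Eb1 at least 131-fold, H2-Aa 121-fold and H2-Ab1 at least 98.0-fold higher. Of the T cell activation and effector list, 10 of 22 genes were at least 4-fold higher, 4 lower and 8 neither. Of the NK cell list, 6 of whose 12 genes the effector list also holds, 4 were higher and 1 lower, with its median at the 98.7th percentile of random lists. Gzma, a granule protease of cytotoxic lymphocytes, had a signal of 17900 on TDC against 12.8 on T (at least 157-fold), and Gzmb, of the same family, was at least 24.5-fold higher. Pdcd1, an inhibitory receptor, was at least 20.7-fold lower. Of the T cell receptor list 11 of 21 genes lay within 4-fold, 8 were lower and 2 higher on TDC, where 54.4% of all 8500 measured genes lay within 4-fold. Over all genes, 1703 were at least 4-fold higher on TDC and 2169 at least 4-fold higher on T, of which 1008 and 1294 were below background on the dimmer array.

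By the naming rule, the other genes highest above T were Adam23, a cell surface protein of the disintegrin family (at least 117-fold), Cpeb4, which binds messenger RNA (at least 110-fold), and Bcr, a regulator of small GTPases (at least 110-fold). Ccnh, a cyclin of the transcription machinery, was 109-fold higher, Dusp5, a phosphatase of MAP kinases, at least 107-fold, and Fscn1, the actin bundler of mature dendritic cells, 105-fold. The genes lowest against T were Ctso, a cathepsin (at least 90.2-fold), Trim56 (71.0-fold), Sntb1 (70.6-fold), Zfp451 (at least 67.7-fold), Ssbp2 (at least 66.7-fold) and Kat2b, a histone acetyltransferase (at least 66.6-fold). They were followed by Gnb4, a G protein subunit (at least 66.3-fold), Smyd4 (at least 64.9-fold), the urea transporter Slc14a1 (at least 63.4-fold) and Rras2 (at least 63.3-fold). With the mean of all probe sets the log2 difference was -1.35 for Bcr and 0.27 for Gnb4, so that both changed direction.

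Of the core dendritic cell list, 7 of 17 genes were at least 4-fold higher on TDC than on T, with Itgax at least 60.1-fold and Flt3 at least 17.8-fold, and 3 were lower, among them Irf4, a transcription factor, by at least 31.4-fold. The type 1 and type 2 lists had 4 of 14 and 5 of 13 genes higher and 1 lower each, with Irf8, a factor needed for type 1 cells, at least 22.7-fold and Csf1r, a receptor of the macrophage lineage, 30.9-fold. The costimulation list had 5 of 14 higher and 1 lower, with Cd83 at least 43.5-fold, and the pattern recognition list 3 of 20 higher and 3 lower. T lineage factors were mostly within 4-fold (9 of 11), and so were the naive T cell genes (6 of 8). Immediate early and stress genes were at least 4-fold higher for 11 of 23 genes and lower for 1, with Nr4a2 at least 95.3-fold and Fos 17.7-fold. Cell cycle genes were higher for 10 of 24 and lower for 1, with Ube2c at least 37.6-fold, Cenpf at least 35.2-fold and Cdc20 at least 10.7-fold. Of the interferon-stimulated list 7 of 14 were lower and 2 higher, with Ifit1 at least 48.5-fold lower. The medians of the costimulation, pattern recognition and interferon-stimulated lists lay within the central 95% of random lists. The neutrophil list had a median log2 difference of 0.77, with 10 of 11 genes within 4-fold.

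In place of a test, 9 of 36 lists had a median above the central 95% of random matched lists and 0 below it, where the 9 again include the sort markers. The effector list lay at the 99.8th percentile, with a median of 1.69 (0.64 with values below background raised to it). Probe sets of one gene had an SD of 1.56 (0.95 as the median over genes), and such noise alone gave 1368 higher and 579 lower calls in simulated unchanged genes (190 and 92 with the median SD). The count of 1703 genes higher on TDC thus exceeds what the pooled noise gives by little, and what the median SD gives by more. The 2169 lower genes are more than either gives. Where called genes had at least 2 detected probe sets, all agreed by at least 1 (log2) for 322 of 468 higher and 477 of 634 lower genes. Of all calls, 44.0% were higher on TDC, 49.4% after quantile normalisation and 34.8% after scaling to the hybridisation controls.

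The comparison of TDC with DC asks the same against dendritic cells. T cell receptor genes were higher on the TDC array: 16 of 21 were at least 4-fold higher and 1 lower. Zap70, the kinase recruited to the activated receptor, had a signal of 19048 on TDC against 86.5 on DC (at least 179-fold), Cd3e was 139-fold, Cd247, the zeta chain, at least 97.8-fold, Cd3g at least 77.8-fold and Cd28 at least 72.9-fold higher. T lineage factors were higher for 7 of 11 genes and lower for 0, with Lef1 at least 139-fold, Bcl11b at least 109-fold and Gata3 at least 10.3-fold. Of the MHC class II list 10 of 14 genes were within 4-fold and 4 were lower on TDC, namely Marchf1 (at least 34.0-fold), H2-Oa (26.9-fold), Lgmn (at least 4.42-fold) and Cd9 (at least 4.38-fold). Over all genes, 1126 were at least 4-fold higher on TDC and 3083 at least 4-fold higher on DC, of which 494 and 2150 were below background on the dimmer array.

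By the naming rule, the genes highest above DC were, beside these, Gzma (132-fold), Neil1, a DNA repair glycosylase (at least 110-fold), and Afap1, which binds actin filaments (at least 104-fold). Coa7, a mitochondrial assembly factor, was at least 102-fold and Atp10a, a lipid flippase, at least 96.4-fold higher. The genes lowest against DC were Tns3, a focal adhesion protein (at least 65.5-fold), Mef2c, a transcription factor (at least 57.7-fold), and Il1b, an inflammatory cytokine (50.4-fold). Rasgef1b was at least 49.4-fold, St8sia1, a ganglioside synthase, at least 49.2-fold, Irf4 at least 47.9-fold, Ube2e2 at least 47.4-fold and Usp6nl at least 44.7-fold lower. Trps1 and the ion transporter Slc12a2 were 42.6-fold and 41.5-fold lower.

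Innate sensing genes were lower on TDC than on DC. Of the pattern recognition list 13 of 20 genes were at least 4-fold lower and 1 higher, with Clec7a, the receptor of fungal glucans, 34.2-fold, Ifih1, an RNA sensor, at least 22.1-fold and Tlr3, another RNA sensor, at least 19.0-fold lower. Of the interferon-stimulated list 10 of 14 were lower and 1 higher, with Rsad2 at least 29.5-fold and Ifit3 at least 14.3-fold. The core dendritic cell list had 8 of 17 genes lower, among them Zbtb46, a factor of the conventional lineage, by at least 21.6-fold and Spi1 by at least 11.9-fold. The costimulation list had 7 of 14 lower, with Cd40 15.4-fold, the lysosome and phagocytosis list 8 of 21, with Cybb 6.93-fold, and the type 1 and type 2 lists 7 of 14 and 6 of 13, with 1 higher each. None of the core, costimulation and lysosome genes was at least 4-fold higher on TDC. The medians of the core, type 2 and costimulation lists lay within the central 95% of random lists, and 32.4% of all measured genes were at least 4-fold lower on TDC. The T cell activation and effector list had 10 of 22 genes higher and 2 lower, with Il2rb at least 39.8-fold, Eomes at least 9.51-fold and Cd40lg at least 8.06-fold. Its median log2 difference was 1.28 as deposited, at the 99.97th percentile of random lists, but -0.03 after scaling to the hybridisation controls. That scaling shifts all genes alike and leaves the percentile of a list unchanged. The neutrophil list had 9 of 11 genes higher and 1 lower, with Ltf 11.1-fold and Lcn2 10.2-fold higher, and the count of higher genes was 2 after that scaling. Of the coreceptors, Cd4 had signals of 2092 on T, 1763 on DC and 1889 on TDC, and Cd8a had 8111, 2876 and 3648. Cd8b1, the beta chain of CD8, had 2913 on T, 2.33 (below background) on DC and 772 on TDC. The order of the arrays for Cd4, and of TDC and DC for Cd8a, depends on the scaling.

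In place of a test, 7 of 36 lists had a median above the central 95% of random matched lists and 5 below it. Probe sets of one gene had an SD of 1.41 (0.92 as the median over genes). Such noise alone gave 1040 higher and 567 lower calls in simulated unchanged genes (201 and 135 with the median SD). The 1126 genes higher on TDC are thus about as many as the pooled noise gives, but more than the median SD gives. The 3083 lower genes are more than either gives. Where called genes had at least 2 detected probe sets, all agreed by at least 1 (log2) for 179 of 316 higher and 850 of 1052 lower genes. Of all calls, 26.8% were higher on TDC, 43.8% after quantile normalisation and 9.60% after scaling to the hybridisation controls. That scaling put the median log2 difference of genes above background on all arrays at -1.28 for TDC against DC, -0.50 for TDC against T and 0.69 for DC against T, where it was 0.03, -0.02 and -0.13 as deposited.

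The place of TDC between the other populations was taken gene by gene, from 0 at the T level to 1 at the DC level on the log2 scale. Genes of the T cell receptor list that were higher on T than on DC lay near T for 15 of 18 genes (place under 1/3) and near DC for 2 (place over 2/3). T lineage factors lay near T for 5 of 6. Genes of the MHC class II list that were higher on DC lay near DC for 7 of 12 and near T for 3, and core dendritic cell genes near DC for 6 of 12 and near T for 3. Without the genes for which the sort selects, these were 4 and 3 of 9 and 5 and 3 of 11. Costimulation genes lay near DC for 5 of 12 and near T for 7, and pattern recognition genes near DC for 4 of 15 and near T for 8. Over all 2793 genes higher on DC, 46.2% lay near T, 21.2% between and 32.6% near DC. Over the 1174 genes higher on T, 28.5% lay near T, 16.3% between and 55.2% near DC. These classes have no outer limit, so for T-high genes near DC includes genes lower on TDC than on DC. The upper quartile of their place was 1.30, where 1 is the DC level. Simulated TDC arrays equal to T or to DC, with noise of SD 0.99 (log2), put 1.84% or 89.1% of the DC-high genes near DC and 86.5% or 2.67% of the T-high genes near T. That SD is of 1 array; with the SD of a difference between arrays (1.56 for T and 1.41 for DC), these values were 6.85% or 81.9% and 77.5% or 7.11%. The genes were selected as high on a single array, so noise on that array alone moves the third array away from it. Across 9960 genes above background on any array, Pearson's r (Spearman's rho) was 0.456 (0.525) for DC with T, 0.545 (0.553) for TDC with T and 0.519 (0.576) for TDC with DC, where genes are not independent replicates.

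**Figure D2:**
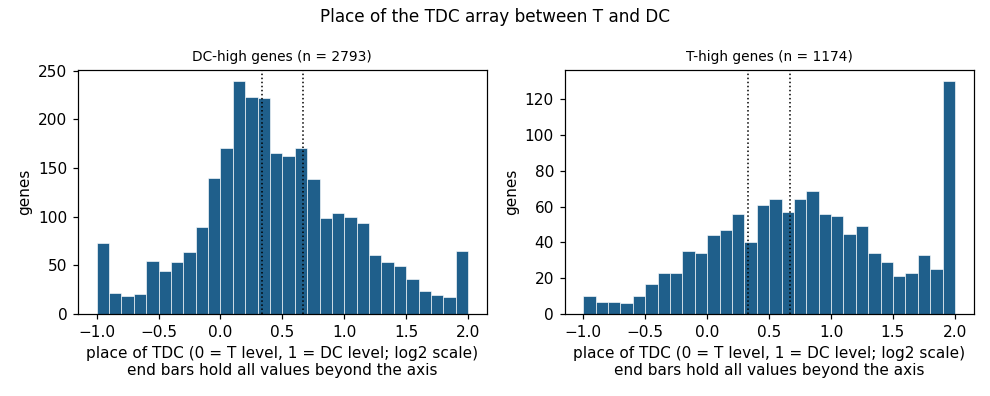
Histograms of the place of the TDC array between the T level (0) and the DC level (1) on the log2 scale, for the 2793 genes at least 4-fold higher on DC and the 1174 at least 4-fold higher on T, with the number of genes on the vertical axis. Dotted lines mark 1/3 and 2/3, and the end bars hold all values beyond the axis; the medians are 0.382 and 0.773.

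On the TDC array 603 genes were at least 4-fold higher than on both other arrays and 1230 at least 4-fold lower than on both. After quantile normalisation these counts were 777 and 782, and after scaling to the hybridisation controls 283 and 1870. The highest were Gzma (132-fold over DC), Coa7 (at least 95.5-fold over T), the transcription factor Nfia (at least 90.7-fold over DC) and Mctp2 (at least 89.3-fold over DC). They were followed by the thiamine transporter Slc19a2 (73.8-fold over DC), Afap1 (68.2-fold over T), Rgmb (at least 61.6-fold over DC), Dsel (at least 60.8-fold over DC), Sag (at least 59.6-fold over DC) and Itm2a (at least 51.7-fold over T). The lowest were St8sia1 (at least 48.7-fold under T), Rras2 (at least 32.1-fold under DC), Irf4 (at least 31.4-fold under T) and Pygb, a glycogen phosphorylase (at least 27.9-fold under DC). Gmcl1 was at least 25.9-fold under DC, Tnfaip8l2 at least 23.8-fold under DC, Glt8d1 at least 23.5-fold under T, Ly75, an endocytic receptor of dendritic cells, at least 22.7-fold under DC and Gnptab at least 21.5-fold under DC. N4bp2l1 had a signal of 209 on TDC against 4387 on DC, but its other probe set, which was below background on T, gave a log2 difference of -0.63 between TDC and DC. On the T array 718 genes were higher than on both others and 974 lower, and on the DC array 1567 and 344. A simulated TDC array that equals T or DC with noise of the pooled SD had 895 or 745 genes higher than both and 310 or 266 lower (155 or 167 and 52 or 48 with the median SD). As deposited, the count of higher genes is thus within what noise of the pooled SD gives but above what the median SD gives. The count of lower genes is above both.

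**Figure D3:**
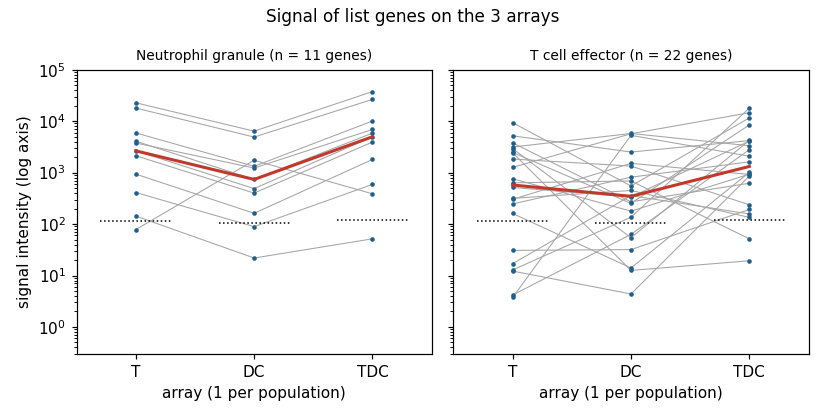
Signal intensity (log axis) of each measured gene of the neutrophil and the T cell activation and effector lists on the T, DC and TDC arrays, 1 array per population. Grey lines join the values of 1 gene, the red line joins the medians and dotted lines mark background; 9 of the 11 neutrophil genes are at least 4-fold higher on TDC than on DC (2 after scaling to the hybridisation controls), and the effector genes cross.

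If the TDC sample were a mixture of RNA of T and DC, the share of the T level kept by T genes and the share of the DC level kept by DC genes would add up to about 1. The T cell receptor list kept a median share of 0.614 over 18 genes and the MHC class II list 0.457 over 12 genes, a sum of 1.07 with a 95% bootstrap interval over genes of 0.477 to 1.99 (0.653 after scaling to the hybridisation controls, and 0.931 without the 3 genes for which the sort selects). The T lineage factors kept 1.36 over 6 genes and the core dendritic cell genes 0.427 over 12, a sum of 1.79 with an interval of 0.843 to 2.72. On the linear scale the median place was 0.115 for DC-high and 0.948 for T-high genes. Selection of genes on single arrays would push these values apart under a mixture as well, by an amount not simulated here, so they were not used to test one. The same selection lowers the shares and their sums, by an amount not measured here.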

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

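Leave-one-out was impossible with 1 array per group, and no paired analysis was possible because each population has a single array. Signal over background limits every fold against a dim array. In simulated data with the median noise, 46% to 54% of genes that differ 4-fold are called. Symmetric noise gives such a value for any difference equal to the cutoff, so it measures no sensitivity. The simulated genes were drawn above background, so they do not show the limit at dim signals. Of the values of the counts, places and shares under alternatives, 83 stayed the same and 48 moved. The rule for counts was wide, so a count called the same could still change. Under quantile normalisation, 1661 genes for T over DC against 1174 as deposited, and 2147 for DC over TDC against 3083, counted as the same. Of 780 values of 157 named differences, 715 stayed the same, 58 moved and 7 reversed. A named difference counted as the same if it kept its sign and shifted by less than the pooled SD between probe sets. That SD was 1.25 for DC with T, 1.56 for TDC with T and 1.41 for TDC with DC. Centring and the hybridisation controls shift all genes of a comparison by 1 constant below it, so their values could only stay or reverse. The mixture sum of T cell receptor and MHC class II genes, 1.07 as deposited, counts as the same because it stayed within its bootstrap interval, but it ran from 0.653 (hybridisation controls) to 1.22 (centred), with 0.931 without the sort marker genes; the other sum was rerun only without those genes (1.69). Counts are given below as genes, and places as the percent of DC-high genes near DC and of T-high genes near T. Quantile normalisation gave 782 genes lower on TDC than both, 38.7% and 35.3%, and centring gave 35.9% for DC-high genes. Background at the median probe set gave 1719 genes for TDC over DC and 36.3% for T-high genes. No background gave 2078 for T over DC, 3506 for TDC over T, 2553 for TDC over DC, 1140 higher than both, 40.8% and 43.2%, because dim genes are counted. The mean of probe sets gave 777 for T over DC, 685 for TDC over DC, 346 higher and 798 lower than both and 27.5% for DC-high genes. Scaling to the hybridisation controls gave 718 for T over DC, 507 for TDC over DC, 4775 for DC over TDC, 283 higher and 1870 lower than both, 20.5% and 22.3%. By construction, 2-fold gave more genes: 2333 for T over DC, 2739 for TDC over T, 2233 for TDC over DC, 1379 higher and 2026 lower than both. Likewise 8-fold gave fewer: 641 for T over DC, 1099 for TDC over T, 1382 for T over TDC, 603 for TDC over DC, 1918 for DC over TDC, 281 higher and 648 lower than both. The linear scale gave 23.1% and 19.8%. Requiring at least 2 agreeing probe sets leaves fewer genes: 755 for DC over T, 245 for T over DC, 322 for TDC over T, 477 for T over TDC, 179 for TDC over DC, 850 for DC over TDC, 69 higher and 203 lower than both, 36.0% and 33.9%. With the mean of probe sets the log2 difference reversed to -1.35 for Bcr and 0.27 for Gnb4 (TDC against T) and to -1.64 for Cd4 (TDC against DC). With the hybridisation controls it reversed to 0.57 (DC against T) and -1.20 (TDC against DC) for Cd4 and to -0.96 for Cd8a (TDC against DC), and with centring to 0.0300 for Cd4 (TDC against T). Where no construction is named, the cause was not tested.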

Other observations

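Of the regulatory T cell list, 4 of 10 genes were at least 4-fold lower on DC than on T and 6 higher on TDC than on DC, with Foxp3, its lineage factor, at signals of 1344 on T, 40.6 (below background) on DC and 632 on TDC. The plasmacytoid list had 5 of 12 genes higher and 1 lower on DC than on T, 3 higher and 2 lower on TDC than on T and 0 higher and 4 lower on TDC than on DC, with Tcf4, its lineage factor, 24.6-fold higher on DC than on T. The Fc and complement receptor list had 4 of 9 higher on DC than on T and 3 lower on TDC than on DC, with Fcgr2b, an inhibitory receptor, 14.2-fold lower. The B cell list had 6 of 10 genes lower on TDC than on DC and 1 higher, with Cd22, an inhibitory receptor of B cells, at signals of 314 on TDC and 4083 on DC. The innate-like and gamma-delta list had 2 of 4 genes higher on TDC than on DC and 1 lower, and the plasma cell list 1 of 6 higher and 3 lower. The progenitor list had 4 of 7 genes higher on DC than on T, with Kit, a growth factor receptor, at least 16.3-fold. The thymocyte list had 2 of 6 higher and 3 lower on TDC than on T, with Tcf12, a transcription factor, at signals of 393 on TDC and 5110 on T. Of all measured genes, 32.4% were at least 4-fold lower on TDC than on DC, and the plasmacytoid and Fc counts were near that share. For TDC against DC, these 2 lists had medians at the 73.3rd and 12.8th percentile of random matched lists, and the plasma cell list at the 22.3rd. The regulatory T cell, innate-like and B cell lists lay farther out, at the 99.96th, 97.45th and 1.64th.

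Of broadly expressed lists, the genes within 4-fold for DC against T, TDC against T and TDC against DC were 28, 29 and 26 of 29 for ribosomal proteins, 29, 27 and 29 of 32 for oxidative phosphorylation and 10, 10 and 12 of 15 for glycolysis. They were 10, 9 and 11 of 12 for housekeeping genes and 13, 11 and 11 of 13 for MHC class I processing. The median of the ribosomal list for DC against T was -0.84, at the 0.69th percentile of random lists. For TDC against DC, 3 of 4 erythroid, 1 of 2 megakaryocyte, 3 of 3 stromal and endothelial and 2 of 3 mast cell and basophil genes were within 4-fold. Of the list that set background, 2 of 6 measured genes were higher and 2 lower. The sort marker list had 4 of 5 measured genes higher and 1 lower on TDC than on T.

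The tests of the receptor and MHC class II sum, of loss by level, of loss of broadly expressed genes, of NK genes with the reading of its interval, and of the neutrophil genes were chosen after the results they measure were seen, while the tests of lineage factors with core dendritic cell genes and of second probe sets were written before. The joint presence of T cell receptor and MHC class II RNA on the TDC array could come from 1 kind of cell that holds both or from a mixture of T and DC in the sorted sample. The shares of the T cell receptor and MHC class II lists summed to 1.07 (95% interval 0.477 to 1.99), and those of the lineage factors and core dendritic cell genes to 1.79 (0.843 to 2.72). Both intervals hold 1, so the explanations cannot be told apart, and the width of the intervals over few genes on 1 array keeps this open, as does the selection of genes as high on T or DC, which lowers both sums by an amount not measured here. A noise-free mixture cannot exceed both of its parts, so a simulated even mixture had, by construction, 0 genes at least 4-fold above both. On TDC there were 603, where noise alone gave 895 or 745 with the pooled SD and 155 or 167 with the median SD. A mixture of the measured T and DC alone thus leaves Gzma unaccounted for (132-fold over DC, on 1 probe set). The noise counts are of genes past 4-fold and do not show how often noise reaches such a fold. The stated purity of at least 99% does not exclude cells sorted as attached pairs, and single-cell measurement would part the explanations.

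The 1230 genes lower on TDC than on both other arrays (782 after quantile normalisation, as against 777 higher) may reflect transcripts lost when little RNA was amplified. Of genes above background on T and DC, 16.5%, 25.3%, 18.9% and 4.55% were at least 4-fold lower on TDC than on both where the dimmer of T and DC had a log2 level of 7 to 8, 8 to 10, 10 to 12 and 12 and above. The ratio of the last to the second value was 0.180, which does not by itself show the cause, so this stays open (17.5% and 10.2% on T and 6.34% and 7.53% on DC at 8 to 10 and at 12 and above). The dimmest genes cannot test a loss that falls with level. A 4-fold drop from 7 to 8 ends below background, where a lost gene need not reach it. The share was also lower at 7 to 8 than at 8 to 10 on T (12.4%) and on DC (3.79%). Of broadly expressed genes 5.77% were at least 4-fold lower on TDC than on both others (3 of 52, where 8.12 were expected and 3 to 13 hold the central 95%), which lies at the edge of what loss alike in all genes would give. Of the 603 genes higher on TDC than on both, 231 have another detected probe set and it was also higher in 37.7%, against 46.9% on T and 80.8% on DC, so many rest on a single probe set, and no biological explanation was tested for either group.

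Genes of the neutrophil list were bright on all 3 arrays. The 2 with the highest signals, chosen after their values were seen, were S100a8 at 17955 on T, 4902 on DC and 26456 on TDC and S100a9 at 22731, 6378 and 37498. As a hypothesis, RNA of granulocyte lineage cells may be present in all 3 samples. The ratio of TDC to T had a median of 1.70 over 11 genes, and 0.06% of random matched lists had as narrow a range. For DC to T, 1.86% of random matched lists did. No measured gene of the list is in another list. The ratio of DC to T had a median of 0.260 (interquartile range 0.186 to 0.303) against 0.329 for the poly-A controls, while TDC to T (1.46 to 1.86) stood against 1.11, and whether a fixed amount of such RNA takes a larger share of a smaller sample cannot be told apart from a true difference, since the amounts of RNA are not given. The cells were sorted on CD11c, MHC class II and T cell receptor beta to a stated purity of at least 99%. That goes against whole neutrophils as the source only if the gates left them out, and the combination of stains is not given. Whether a sort that also excludes Ly6G-positive cells would remove the signal was not tested. Mmp8 and Mmp9 departed from the common ratio.

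As a further hypothesis, NK cell RNA could account for Gzma, the gene highest on TDC above both others. Other cytotoxic genes of the NK list, named after their values were seen, went both ways, with Nkg7 at signals of 2464 on T and 8443 on TDC and Fasl at 3784 and 621. Of the 12 measured NK genes, 6 are also in the effector list, and the other 6 had a median log2 difference of TDC over the higher of T and DC of -0.71 (95% interval -2.92 to 2.18), with 2 at least 4-fold higher, Klra8 at a signal of 585 and Klre1 at 733. Klrd1 and Tyrobp, the genes of these 6 with the highest signals, named after their values were seen, had 4660 and 2457 on TDC against 6692 and 8172 on DC. The explanation cannot be told apart from Gzma expression in the TDC cells, as the interval is wide. A gate on T cell receptor beta would remove NK cells, but whether it was used for TDC is not given in the sources used here. The stated purity therefore cannot decide this, since any cell inside the gate counts as pure.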
